A study of Mus musculus with 4 samples.

How the data were processed

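Gene expression was measured by RNA-seq in 4 libraries of mouse embryonic stem cells, 2 with G784E and 2 with wild-type Smarca4-V5, each beside a wild-type Smarca4-GFP allele. The group and the replicate number of each library were taken from the labels. Nothing in the labels says that replicates came from separate cultures. The p-values of single genes therefore rest on the spread between these libraries, which may be technical. Per the labels' protocols, cells were grown in serum with LIF and left untreated, RNA was extracted with QIAzol, and mRNA was captured on poly(dT), converted to DNA, size-selected and amplified by PCR. The labels list the library source as genomic, although the protocol describes mRNA.

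The authors deposited counts of reads per gene, 1 table per library, in whole numbers and not normalized. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 2.1.0, HTSeq and DESeq2 were used with build mm9. The order of these steps, the gene annotation, the counting mode and the strand setting are not given in the sources used here. Without a strand setting, reads of overlapping and antisense genes cannot be told apart. The summary rows of the tables (no feature, ambiguous, not unique) were left out of library sizes and tests. They held 88.3% and 83.7% of the reads in the G784E tables and 88.7% and 83.3% in the WT tables. Reads not placed uniquely made up 55.4% to 61.8% of each table and reads assigned to no feature 26.5% to 29.5%. Reads shared by close copies of a gene are therefore left out, and how much each gene lost in this way was not tested. The 45S ribosomal RNA gene Rn45s took 16.0% and 10.6% of the gene counts in G784E and 11.9% and 10.0% in WT.

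Gene counts per library were 6226145 and 8895433 (G784E) and 7027108 and 10083442 (WT). A floor of 3 counts corresponded to 0.305 to 0.491 CPM. The widest 95% Wilson interval of a library share had a half-width of 0.0288 percentage points. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Chi-square per degree of freedom over genes was 16.4 between the G784E libraries and 9.62 between the WT libraries, so that no library was a copy of another.

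The main test, chosen before the data were examined like the lists and the naming rule, was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling. Genes were filtered by filterByExpr (minimum count 10, minimum total count 15), which kept 15763 of 24428 genes. The model held group alone, with 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In edgeR, the variance of each gene is drawn towards a trend over all genes, so a gene's p-value does not rest on its own counts alone. CPM values are TMM-scaled. The SE of a log2 fold change was its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.317. Sets were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, over 28 lists with at least 5 tested members, adjusted by Benjamini-Hochberg. Camera compares the genes of a list with the other genes, so its p-values do not measure a spread between cultures. Of 840 listed symbols, 832 were in the tables. Where both the older and the newer symbol of a list entry were present (Tcf3 and Tcf7l1), the newer was used. Of 7 lists past the threshold, 1 kept its call with an estimated correlation and 1 in fry's one-directional test, in both cases the endoderm list.

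Named genes were Smarca4, Smarca2, Pou5f1, Sox2 and Nanog; the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries, leaving out predicted-gene and clone symbols; and up to 2 risen and 2 fallen members of each list with the smallest adjusted p. Other genes are named where a count of 5 or fewer includes them, or as further members of a list, and these were chosen after their values were seen. Results of a few single genes are not reported here.

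Alternatives were RLE and upper-quartile scaling, no filter, a stricter filter (at least 1 CPM in 2 libraries and 50 counts in total), DESeq2 1.42.0, limma-voom, a robust prior, a replicate block, each library left out, and for lists an estimated correlation and fry. With a library left out, the lone library of its group is assumed to vary like the other group, with 1 residual degree of freedom. Chosen after seeing the data were the tests without Rn45s, with a correction for transcript GC content (lowess span 0.3), with that correction and the block together, and on genes at 5 times the background of receptor genes or more. GC content came from the GENCODE M21 annotation of build GRCm38, matched by symbol for 99.3% of tested genes. That build differs from mm9, so no coordinates are given.

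The procedures were tested on simulated counts for the 15763 genes with 200 changed genes. For this comparison edgeR recovered 54% of 2-fold and 97% of 4-fold changes with 5 false calls among 15535 unchanged genes. DESeq2 recovered 47% and 97% with 12 false calls, and limma-voom 52% and 92% with 4. The changed genes were drawn from those with at least 200 counts in total, so the recovery does not cover genes with fewer counts. Camera found the planted list and none of the other 27. Simulated genes varied independently of one another, so this cannot show whether camera's preset correlation suits the real data. The simulated libraries also lacked the structure that real libraries with the same replicate number share. The recovery and the false calls therefore need not hold for the real comparison. Figures were drawn with matplotlib 3.10.9.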

Results

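RNA-seq was used to ask how a heterozygous G784E change in Smarca4, the ATPase of the BAF (mammalian SWI/SNF) chromatin remodelling complex that the study's title calls dominant-negative, altered gene expression in mouse embryonic stem cells. The cells, of strain 129SvEv, carried a wild-type Smarca4 allele fused to GFP. The other allele was fused to the V5 epitope tag and was either wild-type (WT) or G784E. Each group had 2 libraries of poly(dT)-captured RNA, 4 in all. The G784E libraries held 6226145 and 8895433 counts in genes and the WT libraries 7027108 and 10083442, so that 1 count stood for 0.102 to 0.164 CPM (TMM-scaled counts relative to library size). Reads in olfactory receptor genes, which stem cells are not known to express, reached 685 and 684 CPM before scaling in replicate 1 of G784E and WT, and 282 and 193 CPM in replicate 2. Levels are given as mean CPM ± SD with n = 2 per group, and log2 fold changes as G784E over WT with the standard error (SE).

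Smarca4 itself stood at 3868 and 3580 CPM in the G784E libraries and at 2423 and 2553 CPM in the WT libraries, counts in which the WT and G784E alleles cannot be told apart. The log2 fold change was 0.58 (SE 0.19), and it did not pass edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.119). It passed in DESeq2 (0.58, adjusted p = 0.00808), in limma-voom (0.58, adjusted p = 0.03) and in edgeR with upper-quartile scaling (0.59, adjusted p = 0.0108). The adjusted p over the alternatives that model the group alone, DESeq2 and limma-voom included, ran from 0.00808 to 0.764. Smarca2, which encodes the alternative ATPase of the complex, fell from 41.2 ± 0.718 CPM in WT to 8.0 ± 0.487 CPM in G784E, 5.16-fold lower (log2 fold change -2.37, SE 0.26; edgeR, adjusted p = 3.1e-06). Of 27 tested genes for BAF subunits, Smarca2 was the 1 that fell, also when adjusted over the list alone, and the other 26 did not pass the test. The list as a set had a median log2 fold change of 0.07 (camera, adjusted p = 0.292). Whether Smarca2 fell within the stem cells or through a change in the cells present was not tested. Among the 31 tested Polycomb subunits, Pcgf5 fell 3.16-fold, from 14.6 ± 3.10 to 4.69 ± 2.63 CPM (edgeR, adjusted p = 0.024), and was also the 1 gene adjusted over the list alone. Pcgf5 did not pass without G784E replicate 2 (log2 fold change -1.13, edgeR, adjusted p = 0.0827), without WT replicate 1 (-1.42, adjusted p = 0.364), in DESeq2 (-1.65, adjusted p = 0.0627), with upper-quartile scaling (-1.65, adjusted p = 0.087) or among genes above background (-1.69, adjusted p = 0.0529). Its edgeR log2 fold change of -1.66 was -2.34 without G784E replicate 1. The Polycomb list had a median of 0.09 (camera, adjusted p = 0.165), which passed without WT replicate 2 (0.16, adjusted p = 0.0236).

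Genes of the early endoderm and its basement membrane were among the largest decreases in G784E cells, and a mixed set of genes rose. Cubn and Lrp2, which encode the endocytic receptors cubilin and megalin of visceral endoderm, fell 25.6-fold (378 ± 40.6 to 14.7 ± 1.56 CPM) and 14.3-fold (432 ± 71.0 to 30.2 ± 0.316 CPM). The endoderm transcription factors Sox17 and Gata6 fell 17.4-fold and 13.3-fold, and the type IV collagen genes Col4a1 and Col4a2 fell 13.9-fold and 13.2-fold. The other 4 genes with the steepest decreases under the naming rule were Srgn (serglycin, a proteoglycan; 22.9-fold), Stard8 (17.0-fold), Chst15 (a chondroitin sulfotransferase; 16.4-fold) and Cemip (a hyaluronan-binding protein; 13.9-fold). In the other direction, Dmrt1, a transcription factor of gonad and germ cells, rose 7.93-fold from 3.15 ± 0.717 to 25.4 ± 6.43 CPM. It was followed by Ak7 (4.77-fold), the activin subunit gene Inhbb (4.0-fold), Fgf17 (3.87-fold), the synaptonemal complex gene Sycp1 (3.82-fold), the Wnt potentiator Rspo1 (3.71-fold) and Rragd (3.55-fold). The neurofilament gene Nefh (3.35-fold; 34.4 ± 0.864 to 115 ± 16.04 CPM), Clca3b (3.24-fold) and the titin gene Ttn (3.10-fold; 178 ± 32.5 to 552 ± 78.2 CPM) completed the 10.

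In all, 404 of 15763 tested genes differed between the groups in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 298 were lower in G784E, 240 of them by 2-fold or more, and 106 were higher, 62 of them by 2-fold or more. DESeq2 called 260 lower and 108 higher, and limma-voom called 364 lower and 186 higher. With a single library left out, the numbers lower and higher were 404 and 187 (without G784E replicate 1), 532 and 307 (without G784E replicate 2), 156 and 29 (without WT replicate 1) and 179 and 77 (without WT replicate 2). Among the 20 genes named for the size of their change, the edgeR call was lost without WT replicate 2 for Ak7 (log2 fold change 1.72, adjusted p = 0.289), Sycp1 (1.90, adjusted p = 0.205) and Clca3b (1.68, adjusted p = 0.108). It was lost without WT replicate 1 for Sycp1 (1.96, adjusted p = 0.131) and Clca3b (1.71, adjusted p = 0.0747), without G784E replicate 1 for Clca3b (1.42, adjusted p = 0.0806) and without G784E replicate 2 for Sycp1 (1.81, adjusted p = 0.168). Upper-quartile scaling also ended the calls of Ak7 (2.23, edgeR, adjusted p = 0.0666) and Sycp1 (1.93, adjusted p = 0.0612). The log2 fold change of Ak7, 2.25, was 3.03 without WT replicate 1, and that of Sox17, -4.12, was -4.71 without G784E replicate 2. Chst15, at -4.04, did not pass in DESeq2 (-3.94, adjusted p = 0.185), and was -2.95 in edgeR without G784E replicate 2. Without G784E replicate 1, the remaining G784E library held 1 count of Chst15, and no fold is given.

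**Figure D1:**
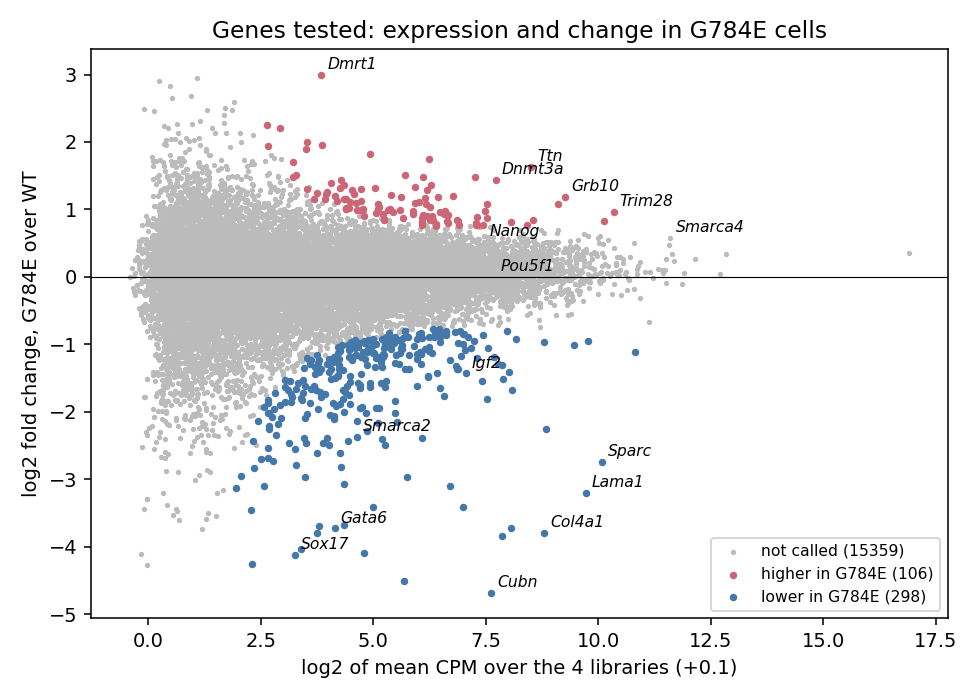
Log2 fold change of G784E over WT (vertical axis) against the log2 of the mean CPM over the 4 libraries (horizontal axis) for the 15763 tested genes, 1 point per gene. Blue marks the 298 genes lower in G784E and red the 106 higher; Cubn lies at -4.68 and Dmrt1 at 2.99.

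Primitive and definitive endoderm genes, tested together as 1 list, fell as a group. Of 24 tested members, 16 fell (19 lower and 1 higher adjusted over the list alone) and 8 did not pass, with a median log2 fold change of -2.62 (camera, adjusted p = 3.14e-128; adjusted p = 0.038 with an estimated correlation). The median was -2.40 within the libraries numbered 1 and -3.01 within those numbered 2. Col4a1 fell from 832 ± 20.9 to 59.9 ± 4.31 CPM (log2 fold change -3.80, SE 0.22; edgeR, adjusted p = 5.34e-11), Cubn had a log2 fold change of -4.68 (SE 0.24; adjusted p = 1.02e-11), Gata6 of -3.73 (SE 0.32; adjusted p = 4.05e-08) and Sox17 of -4.12 (SE 0.47; adjusted p = 3.91e-06). The laminin genes Lama1, Lamb1 and Lamc1 were 9.23-fold, 4.76-fold and 2.16-fold lower, the matrix gene Sparc 6.71-fold, Dab2 10.7-fold, Podxl 8.56-fold, Gata4 10.6-fold and Pdgfra 4.40-fold. Foxq1, at -2.07, was -3.65 without G784E replicate 1, and did not pass without G784E replicate 2 (log2 fold change -1.25, edgeR, adjusted p = 0.148), without WT replicate 1 (-2.11, adjusted p = 0.11) or without WT replicate 2 (-2.0, adjusted p = 0.298). Foxa2 and Hnf4a (-3.01 and -2.32) and, in the opposite direction, Foxa1 (2.40) were among those that passed over the list alone. Fst (-1.07, SE 0.58), Cxcr4 (-0.14, SE 1.18), Apoe (-0.04, SE 0.21) and Afp (0.79, SE 1.33) did not pass in either way. Apoe stood at 67.6 ± 3.80 CPM in WT and 65.4 ± 8.76 CPM in G784E, so the fall did not extend to Apoe. Cxcr4, Afp and Foxa1 stood at 1.67, 1.06 and 0.995 CPM in WT, too low for a fall to be seen clearly. Definitive endoderm was not tested apart. Feeder fibroblast markers, a list of another cell type that such cultures can hold, had a median of -0.16 (camera, adjusted p = 0.558), with 1 of 19 tested members, Cald1, 1.94-fold lower (edgeR, adjusted p = 0.00666), also the 1 adjusted over the list alone. Cald1 did not pass without WT replicate 1 (log2 fold change -0.90, adjusted p = 0.0801 in edgeR).

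**Figure D2:**
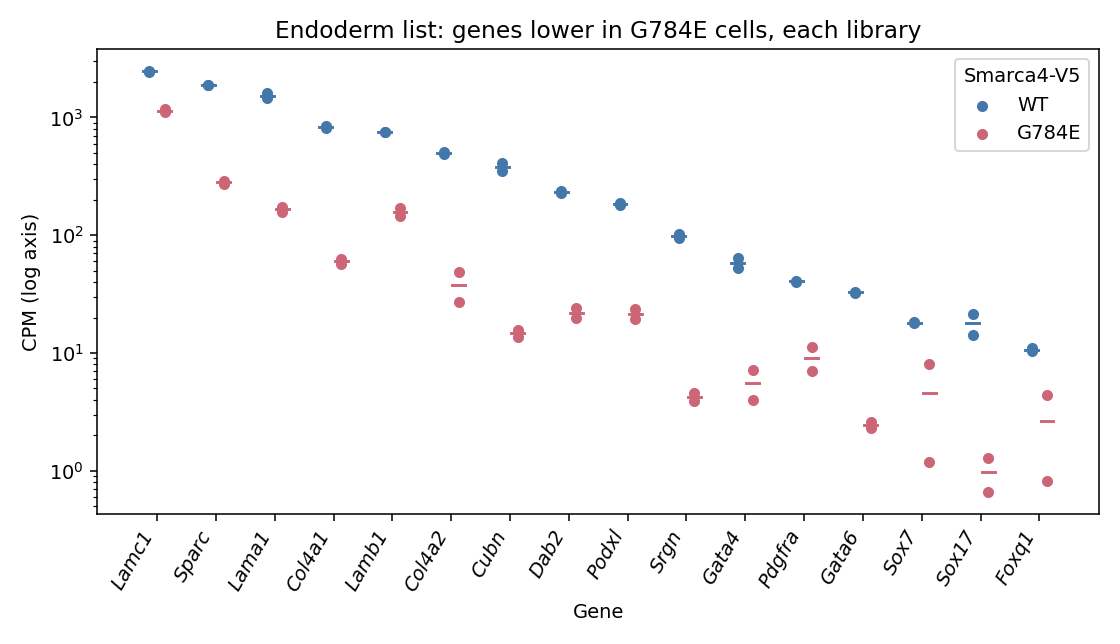
CPM on a log axis of the 16 endoderm genes that were lower in G784E, 1 point per library and a bar at each group mean, WT in blue and G784E in red. For Col4a1 the group means are 832 and 59.9 CPM, and for Cubn 378 and 14.7 CPM.

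Trophectoderm genes also lay lower in G784E. Of 22 tested members, 4 fell (7 lower and 2 higher adjusted over the list alone): Tinagl1 (6.09-fold) and the keratin genes of simple epithelium Krt18 (3.83-fold; 40.9 ± 2.35 to 10.7 ± 0.258 CPM; edgeR, adjusted p = 2.92e-05), Krt19 (3.27-fold) and Krt8 (2.93-fold). The median was -0.77 (camera, adjusted p = 3.09e-05; adjusted p = 0.337 with an estimated correlation), at -0.54 and -0.91 within the libraries numbered 1 and 2. The endoderm list fell in the same comparison (median -2.62), and the fibroblast list, at a median of -0.16, did not pass. The trophoblast transcription factor genes Elf5, Ascl2, Gata3, Msx2, Gcm1, Cdx2, Tfap2a, Gata2, Tfap2c and Dlx3 did not pass over all genes. Their log2 fold changes ran from -1.73 (Elf5) to 1.15 (Dlx3) with SEs of 0.24 to 1.36. Krt8 did not pass without G784E replicate 2 (log2 fold change -1.30, edgeR, adjusted p = 0.0599), WT replicate 1 (-1.63, adjusted p = 0.143) or WT replicate 2 (-1.45, adjusted p = 0.387). Peg10, Plet1 and Rhox6 were the further lower members over the list alone (-0.67, -1.13 and -1.67), and Dlx3 and Tfap2c the higher ones (1.15 and 0.65).

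Genes of the other lineages mostly did not pass the test. In the primitive streak and mesoderm list, Eomes, a T-box factor of streak and trophoblast, fell 3.30-fold from 16.5 ± 0.526 to 4.92 ± 1.87 CPM (edgeR, adjusted p = 0.00642), the 1 of 12 tested members called. Adjusted over the list alone, 2 were lower (Eomes and Tbx20) and 1 higher (Mesp2, at 2.13), and the list median was -0.08 (camera, adjusted p = 0.264). Eomes did not pass without WT replicate 2 (-1.69, edgeR, adjusted p = 0.0982). In the neural ectoderm list, Stmn2, a microtubule regulator of neurons, rose 1.83-fold from 129 ± 9.66 to 236 ± 25.4 CPM (edgeR, adjusted p = 0.0146), 1 of 20 tested and also the 1 adjusted over the list alone. The list's median and mean were below 0 (-0.08 and -0.04) while camera's direction was up (adjusted p = 0.632). Stmn2 did not pass without WT replicate 1 (0.80, edgeR, adjusted p = 0.238) or WT replicate 2 (0.95, adjusted p = 0.0528). The 23 tested developmental regulators known as Polycomb targets had a median of -0.18 (camera, adjusted p = 0.375). Camera passed without G784E replicate 1, at a median of -1.33, and without WT replicate 2, at -0.94. The median turned to 0.68 without WT replicate 1 and was also above 0 without G784E replicate 2, and camera did not pass in either case. Leaving out 1 library leaves replicate 1 and replicate 2 unequally represented in the groups. Olfactory receptor reads were higher in replicate 1 of both groups, so these moves of the median cannot be told apart from that background.

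The core pluripotency factors did not pass the test. Pou5f1 stood at 207 ± 44.3 CPM in WT and 208 ± 29.4 CPM in G784E (log2 fold change 0.01, SE 0.21; edgeR, adjusted p = 1), Sox2 at 155 ± 8.85 and 174 ± 29.9 CPM (0.16, SE 0.20; adjusted p = 0.929) and Nanog at 144 ± 15.5 and 207 ± 28.4 CPM (0.52, SE 0.20; adjusted p = 0.252). In the general pluripotency list, 2 of 20 tested genes rose (3 adjusted over the list alone, with Dppa2 at 0.85). These were the co-repressor gene Trim28 (1.95-fold; 880 ± 192 to 1713 ± 189 CPM; edgeR, adjusted p = 0.00806) and the elongation factor gene Tcea3 (2.30-fold; adjusted p = 0.0237). The list's median was 0.25 (camera, adjusted p = 0.00319; adjusted p = 0.708 with an estimated correlation), and camera did not pass without WT replicate 1 (0.15, adjusted p = 0.261). Trim28 did not pass without WT replicate 1 either (0.75, edgeR, adjusted p = 0.133), nor with no filter (0.92, adjusted p = 0.0556). Tcea3 did not pass without WT replicate 1 (1.00, edgeR, adjusted p = 0.372), without G784E replicate 1 (0.87, adjusted p = 0.113), in DESeq2 (1.21, adjusted p = 0.0708), with upper-quartile scaling (1.23, adjusted p = 0.0573) or among genes above background (1.18, adjusted p = 0.0527). Among 20 naive pluripotency genes, Jam2 rose 1.74-fold (edgeR, adjusted p = 0.0366), a call lost without WT replicate 1 (0.62, adjusted p = 0.617), with RLE scaling (0.80, adjusted p = 0.0574), with no filter (0.76, adjusted p = 0.082) and without Rn45s (0.77, adjusted p = 0.0558). Adjusted over the list alone, 3 of these were higher (Jam2, Gbx2 and Nr5a2) and 2 lower (Fgfbp1 and Pecam1). The naive median was 0.11 (camera, adjusted p = 0.248), which passed without G784E replicate 1 (0.19, adjusted p = 0.0294).

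Genes of formative and primed pluripotency moved in both directions. The de novo DNA methyltransferase gene Dnmt3a rose 2.70-fold, from 115 ± 9.50 to 309 ± 1.91 CPM (log2 fold change 1.43, SE 0.20; edgeR, adjusted p = 7.88e-05). Its cofactor gene Dnmt3l fell 2.56-fold, from 74.7 ± 5.35 to 29.1 ± 4.06 CPM (-1.36, SE 0.22; adjusted p = 0.000399 in edgeR). Car4 (3.33-fold) and Otx2 (1.86-fold) also fell, so that 1 of 17 tested members rose and 3 fell (2 higher, with Tcf15 at 0.87, and 3 lower adjusted over the list alone). The median was 0.07 and the mean -0.09, and camera's direction was down (adjusted p = 0.713). Car4 did not pass without WT replicate 1 (-1.41, edgeR, adjusted p = 0.511), nor Otx2 without WT replicate 2 (-0.74, adjusted p = 0.267).

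Among signalling genes, Nodal and Inhbb rose and Id2 fell. Of 13 tested Nodal and BMP targets, Inhbb (4.0-fold; edgeR, adjusted p = 0.000931), Nodal (2.33-fold; 25.0 ± 3.25 to 58.4 ± 7.24 CPM; adjusted p = 0.00209) and the pseudoreceptor gene Bambi (2.79-fold; adjusted p = 0.0325) rose, and Id2 fell 6.62-fold (adjusted p = 0.00403). The log2 fold change of Id2, -2.73, was -3.77 without G784E replicate 1 and -2.03 without G784E replicate 2. The same 3 higher and 1 lower passed adjusted over the list alone. The list's median was -0.01 and its mean 0.05, with camera's direction up (adjusted p = 0.248). Nodal did not pass without WT replicate 2 (1.09, edgeR, adjusted p = 0.0558), and Bambi did not pass without G784E replicate 2 (1.17, adjusted p = 0.25), WT replicate 1 (1.42, adjusted p = 0.238) or WT replicate 2 (1.55, adjusted p = 0.169). Of 13 tested LIF and STAT3 targets, Myc rose 2.79-fold, from 80.4 ± 35.2 to 225 ± 7.12 CPM (edgeR, adjusted p = 0.000455). Adjusted over the list alone, 3 of these were higher (Myc, Pim1 and Bcl3) and 1 lower (Lifr), with a median of 0.02 (camera, adjusted p = 0.242). Of 15 tested FGF and ERK targets, the phosphatase gene Dusp4 fell 2.47-fold (edgeR, adjusted p = 0.00719), with a log2 fold change of -1.30 that was -0.86 without G784E replicate 2. Adjusted over that list alone, 3 were higher (Spred2, Etv5 and Etv4) and 2 lower (Dusp4 and Phlda1), and its median of -0.13 and mean of -0.04 lay below 0 while camera's direction was up (adjusted p = 0.652).

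Germline genes lay higher in G784E. Of 33 tested members, 4 rose (5 adjusted over the list alone, with Mael added): the RNA helicase genes Ddx4 (2.19-fold; 16.5 ± 0.928 to 36.1 ± 4.36 CPM; edgeR, adjusted p = 0.00883) and Mov10l1 (2.22-fold; adjusted p = 0.0133), and the synaptonemal complex genes Syce1 (2.17-fold) and Sycp1 (3.82-fold). The median was 0.50 (camera, adjusted p = 0.00198; adjusted p = 0.35 with an estimated correlation), at 0.36 and 0.37 within the libraries numbered 1 and 2. Each of these 4 calls was lost when a WT library was left out: edgeR's adjusted p without WT replicate 1 was 0.169 for Ddx4 (log2 fold change 1.08), 0.202 for Mov10l1 (1.10), 0.358 for Syce1 (1.01) and 0.131 for Sycp1 (1.96). Without WT replicate 2 it was 0.0739 for Ddx4 (1.19), 0.108 for Mov10l1 (1.20), 0.117 for Syce1 (1.25) and 0.205 for Sycp1 (1.90), and Syce1 was also lost without G784E replicate 1 (0.95, adjusted p = 0.0562).

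Imprinted genes changed in both directions. Igf2, a paternally expressed growth factor gene, fell 2.70-fold from 194 ± 5.40 to 72.1 ± 6.74 CPM (log2 fold change -1.43, SE 0.20; edgeR, adjusted p = 9.27e-05). The growth regulator gene Grb10 rose 2.28-fold from 375 ± 60.7 to 854 ± 125 CPM (1.19, SE 0.21; adjusted p = 0.000969 in edgeR), Mest rose 1.85-fold (adjusted p = 0.0212) and Phlda2 1.99-fold (adjusted p = 0.0483). Of 33 tested members, 3 rose and 1 fell (4 higher and 3 lower adjusted over the list alone, with Impact at 0.70, Sgce at -1.30 and Slc38a4 at -0.60), and the median was -0.18 (camera, adjusted p = 0.632). Mest did not pass without WT replicate 1 (0.66, edgeR, adjusted p = 0.532), nor Phlda2 without WT replicate 1 (0.75, adjusted p = 0.676) or G784E replicate 1 (0.66, adjusted p = 0.199).

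The called genes of the hypoxia and glycolysis list were collagen-modifying enzymes. Of 25 tested genes, the collagen prolyl 4-hydroxylase genes P4ha2 (5.42-fold; 36.6 ± 2.78 to 6.76 ± 0.394 CPM; edgeR, adjusted p = 3.7e-06) and P4ha1 (3.58-fold; adjusted p = 0.000147) fell. The log2 fold change of P4ha1, -1.84, was -2.44 without G784E replicate 1. Adjusted over the list alone 7 were lower, with Egln3, Pfkp, Vegfa, Hk1 and Pfkl between -0.97 and -0.60. The median was -0.36 (camera, adjusted p = 4.4e-06; adjusted p = 0.337 with an estimated correlation). The endoderm list (median -2.62) and the type IV collagen genes fell in the same comparison. In the cholesterol synthesis list, Pmvk, a mevalonate pathway kinase gene, fell 2.06-fold (edgeR, adjusted p = 0.0258), 1 of 23 tested and also the 1 adjusted over the list alone, with a list median of -0.35 (camera, adjusted p = 0.00312; adjusted p = 0.35 with an estimated correlation). Pmvk did not pass without WT replicate 1 (-1.19, edgeR, adjusted p = 0.0783), without WT replicate 2 (-0.87, adjusted p = 0.429) or in DESeq2 (-1.04, adjusted p = 0.0723).

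Atf4, the transcription factor gene at the centre of the amino acid and endoplasmic reticulum stress response, rose 1.97-fold from 121 ± 4.56 to 238 ± 19.3 CPM (edgeR, adjusted p = 0.0054), and did not pass without WT replicate 1 (0.94, adjusted p = 0.0825). It was the 1 of 24 tested members called (4 higher and 1 lower adjusted over the list alone, with Trib3 at 1.51, Shmt2 at 0.67, Slc7a5 at 0.59 and Cth at -0.81). The median was 0.25 (camera, adjusted p = 0.00991; adjusted p = 0.424 with an estimated correlation), and camera did not pass without G784E replicate 2 (0.34, adjusted p = 0.093) or WT replicate 2 (0.16, adjusted p = 0.061). Of 24 tested p53 targets, the apoptosis effector gene Perp fell 1.71-fold (edgeR, adjusted p = 0.0345), and 4 were lower adjusted over the list alone (with Cdkn1a, Btg2 and Eda2r), at a median of -0.09 (camera, adjusted p = 0.242). Perp did not pass without G784E replicate 1 (-0.72, edgeR, adjusted p = 0.0524), WT replicate 1 (-0.77, adjusted p = 0.291) or WT replicate 2 (-0.79, adjusted p = 0.188), nor with RLE scaling (-0.77, adjusted p = 0.0552) or GC correction (-0.72, adjusted p = 0.0998).

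In the other 8 lists, of two-cell-like, Hox, Wnt and beta-catenin target, cell cycle, interferon-stimulated, heat shock and immediate early, ribosomal protein and replication-dependent histone genes, 0 of 221 tested members passed edgeR's quasi-likelihood test. At an unadjusted p under 0.05, 12 of them were higher and 9 lower, while DESeq2 called 3 and limma-voom 4. Adjusted over the list alone, the Wnt list had 1 higher gene (Ccnd1, at 0.75) and 1 lower gene (Dkk1, at -3.74), and the others had 0. The medians were 0.84 for two-cell-like genes, -0.13 for Hox, 0.07 for Wnt, 0.03 for cell cycle, -0.12 for interferon-stimulated, 0.10 for heat shock, 0.03 for ribosomal protein and -0.15 for histone genes, with camera's adjusted p between 0.242 and 0.904. The Wnt mean was -0.06, opposite in sign to its median. Camera passed for two-cell-like genes when no expression filter was applied (0.92, adjusted p = 0.00703). Without G784E replicate 1 it passed for Hox genes, at a median of -1.45, and cell cycle genes, at 0.15. The Hox median turned to 0.78 without WT replicate 1 and was also above 0 without G784E replicate 2. The two-cell-like median ran from 0.21 without WT replicate 2 to 1.85 without WT replicate 1. With a library left out, these Hox and two-cell-like moves cannot be told apart from the higher olfactory receptor background of replicate 1. Two-cell-like, ribosomal protein and histone genes have close copies, so the uniquely placed reads counted here are an uncertain measure of them.

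**Figure D3:**
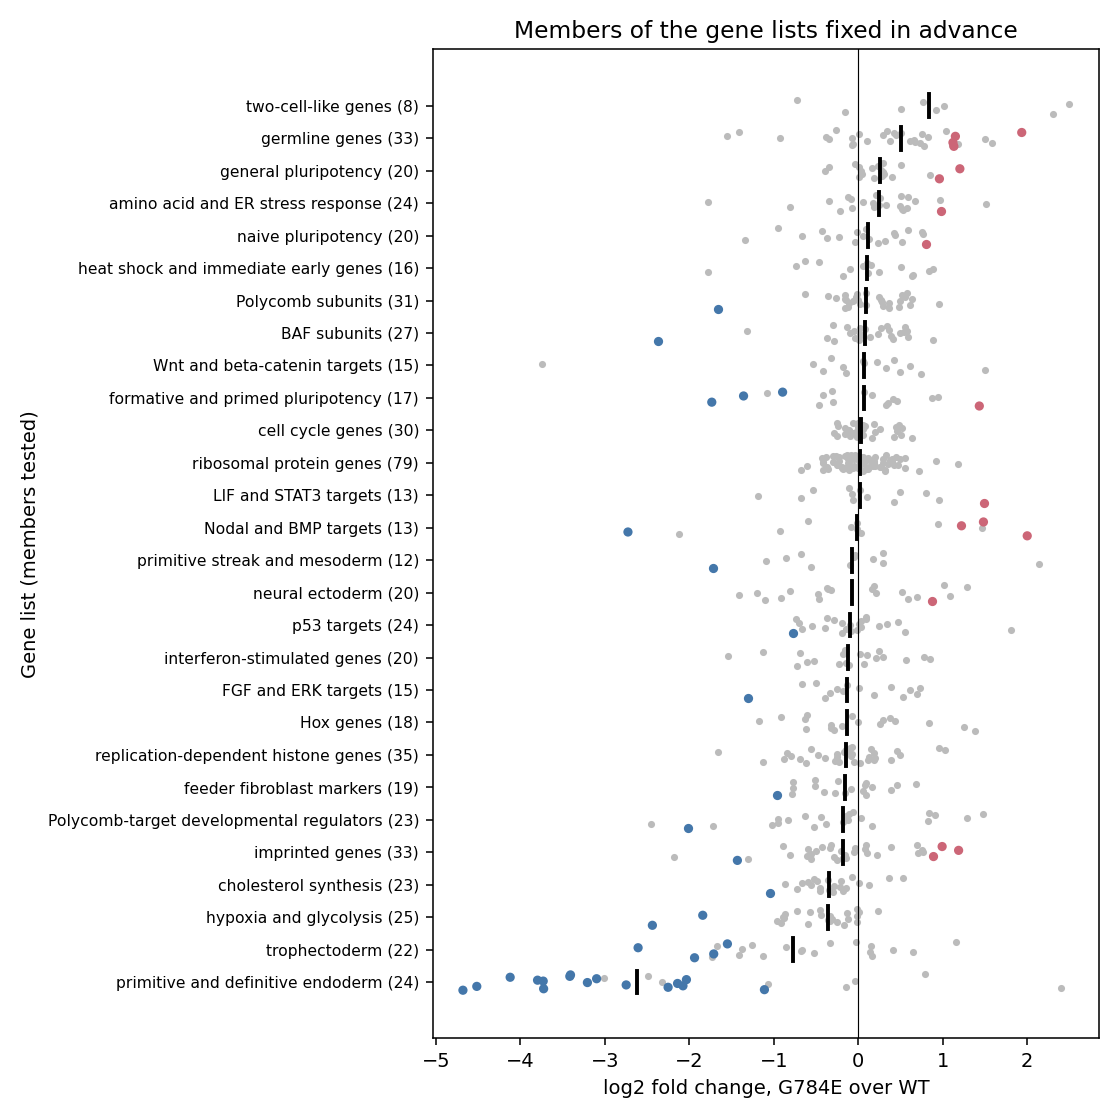
Log2 fold change of G784E over WT (horizontal axis) of each tested member of the 28 gene lists, 1 point per gene and 1 row per list, with a black bar at each list's median. Blue points are lower and red points higher in G784E at an adjusted p under 0.05, and the endoderm list at the bottom has the lowest median (-2.62).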

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

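Tests chosen only after the results were seen were those without Rn45s, with GC correction, with replicate block and GC correction, and on genes above background; the others were planned. Under RLE or upper-quartile scaling, no filter, the stricter filter, DESeq2, the robust prior, without Rn45s, GC correction alone and genes above background, the 4 counts of changed genes stayed within 1.5 times their values. The genes called were not all the same. These fits kept 82 (without Rn45s) to 103 (robust prior) of the 106 higher genes. Of the 298 lower genes they kept 242 (DESeq2) to 297 (no filter). DESeq2 gave no adjusted p for 4279 of the 15763 tested genes. limma-voom called 186 genes higher against 106, and the cause was not tested. Leaving out single libraries gave 29 to 307 genes higher, 156 to 532 lower, 28 to 161 higher by 2-fold or more and 151 to 367 lower by 2-fold or more; the fewer libraries leave 1 residual degree of freedom. Deviations from the group means correlated at 0.487 between libraries of the same number, and the first principal component (53.6% of the variance) separated the numbers. The labels state no pairing. With a replicate block, 546 genes were higher, 658 lower and 104 higher by 2-fold or more; with replicate block and GC correction the counts were 825, 706 and 125, and 362 were lower by 2-fold or more. Higher genes were 45.3% and 53.9% of the calls in these fits, against 26.2% without them. Both blocked fits kept all 106 higher and 298 lower genes. Smarca4 passed at a log2 fold change of 0.59 under upper-quartile scaling, 0.58 in DESeq2, 0.58 in limma-voom, 0.58 with the replicate block and 0.57 with block and GC correction, against 0.58 and an adjusted p of 0.119 in edgeR; the cause was not tested beyond the smaller spread under the block. Nanog passed with the replicate block (0.52, edgeR, adjusted p = 0.0051). Of the 8 lists with 0 called members, the block called 5 cell cycle genes higher, 2 interferon-stimulated genes lower and 1 heat shock gene higher. It also called 1 histone gene lower, 1 gene each way in the Wnt and ribosomal protein lists, and 0 two-cell-like or Hox genes. No called gene among those named, and no called list, changed direction in the settings run. Medians of several lists that were not called, such as the Hox, Polycomb-target, neural ectoderm and FGF lists, changed sign in some settings. Many of the called genes named lost the call when a WT library was left out. The common biological coefficient of variation was then 0.341, against 0.287 without a G784E library and 0.317 in the main fit. A lost call thus need not mean a smaller change: Sycp1, at 1.93, was 1.96 without WT replicate 1. Of the lists, the endoderm median ran from -3.17 to -2.32 and passed in each of 18 settings. At these depths edgeR recovered 54% of simulated 2-fold changes, planted in genes above a count minimum. This limits what the counts show of smaller changes and of genes with few counts.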

Other observations

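The lists of YAP and TEAD targets, collagen processing, neuronal intermediate filaments and RNA polymerase II subunits, and the tests of fibroblasts, library numbers, endoderm-like cells, silent gene families and GC content, were chosen only after the results were seen. The lists were drawn up around genes already called, so no set test of them is given. Several targets of YAP and TEAD, the effectors of Hippo signalling, fell in G784E. Of 21 tested members of a signature of such targets, 10 fell and 11 did not pass edgeR's test, among the former the matricellular genes Cyr61 (2.77-fold; 109 ± 3.46 to 39.4 ± 2.87 CPM, n = 2 per group) and Ctgf (2.69-fold), the coagulation factor gene F3 (5.52-fold) and Ptpn14, Amotl1 and Crim1 (2.27-fold, 2.19-fold and 2.29-fold). The endoderm list, at a median of -2.62, fell in the same comparison. Ankrd1, Myof, Dock5 and Amotl2 also fell (log2 fold changes -1.88, -0.97, -0.86 and -1.21), and their calls depended on single libraries. Without WT replicate 2, edgeR gave Ankrd1 at -2.21 (adjusted p = 0.109), Myof at -1.004 (0.0854), Dock5 at -0.73 (0.202) and Amotl2 at -0.98 (0.195). Without WT replicate 1 it gave Ankrd1 at -1.44 (adjusted p = 0.868) and Myof at -0.93 (0.186), without G784E replicate 2 Ankrd1 at -1.70 (0.0659) and Myof at -0.64 (0.106), and without G784E replicate 1 Dock5 at -0.69 (0.0889).

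Several genes for the processing of collagen fell beside the type IV collagen genes and the endoderm list. Of 26 tested members, 7 fell and 19 did not pass: the collagen chaperone gene Serpinh1 (7.84-fold; 95.5 ± 3.21 to 12.1 ± 2.06 CPM), P4ha1 and P4ha2, which are also in the hypoxia list, the lysyl hydroxylase gene Plod2 (3.19-fold), Loxl2 (3.85-fold), Pxdn (3.10-fold) and P3h2 (3.82-fold). P3h2, at -1.93, lost the call without WT replicate 1 (-1.97, edgeR, adjusted p = 0.289) and WT replicate 2 (-1.90, adjusted p = 0.447), and Pxdn, at -1.63, was -2.31 without G784E replicate 2. Among the 5 neuronal intermediate filament genes, Nefh (3.35-fold) and Ina (2.79-fold) rose and 3 did not pass. Among 11 tested RNA polymerase II subunits, Polr2e (1.99-fold) and Polr2a (1.78-fold; 799 ± 139 to 1421 ± 11.9 CPM) rose and 9 did not pass. Polr2a did not pass without WT replicate 1 (0.66, edgeR, adjusted p = 0.305), and Polr2e did not pass without WT replicate 1 (1.02, adjusted p = 0.108) or WT replicate 2 (0.96, adjusted p = 0.124).

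The decrease of endoderm genes in G784E was weighed against other cell types and library structure. Fewer feeder fibroblasts are argued against by the fibroblast list's median of -0.16 and by the fibrillar collagen genes Col1a1, Col1a2 and Col3a1, which summed to 69.2 CPM in G784E and 54.6 CPM in WT while Col4a1 fell from 832 to 59.9 CPM. Structure shared by libraries of one number is balanced between the groups, since each number has a library of each group, so it cannot by itself give a group difference. The within-number medians of -2.40 and -3.01 show that the fall was not confined to the libraries of one number. Fewer endoderm-like cells in the G784E cultures may account for the pattern and cannot be told apart from lower expression per cell: the 16 called genes fell by unequal folds, from 2.16 to 25.6 (Cochran's Q per degree of freedom 16.6), but the stem cells may express some of them too. Lower expression per cell in the G784E genotype stays open and was not tested. Whether other genes lower in G784E, such as Igf2, Dnmt3l, Otx2, Car4, Eomes, Id2 and Dusp4, fell through a change in the cells present was not tested either.

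Libraries of replicate 1 held more reads in gene families not expected in these cells. As a share of gene counts, olfactory receptor genes were 2.43 times (G784E) and 3.55 times (WT) higher in replicate 1 than in replicate 2, vomeronasal receptor genes 2.02 and 3.44 times, and keratin-associated protein genes 3.67 and 5.07 times. Reads not from mRNA, such as genomic DNA, are a candidate source, since each of the 6 ratios was at least 2.02. No biological explanation was tested. With genes near that background left out, 86 genes were higher and 280 lower.

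The genes higher in G784E were richer in GC than other genes of like expression. Their median GC content was 53.4%, against 48.7% in 10000 random sets matched on expression (one-sided permutation p = 1e-04, the smallest these sets can give), while the genes lower in G784E were at 49.3%, as were their matched sets (49.3%). A GC bias between libraries is argued against as the whole cause, since 90 of the 106 higher genes remained higher after a GC correction, and the 96 genes then called had a median of 52.1%. No biological explanation was tested.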
